A study of mouse gut metagenome with 60 samples.

How the data were processed

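The study sorted faecal bacteria of mice by whether they carried immunoglobulin A (IgA) on their surface and sequenced the 16S rRNA gene of each fraction, an assay known as IgA-seq. DOCK8 is a guanine nucleotide exchange factor expressed in blood cells, and the series title ties it to the metabolic fitness of IgA-producing plasma cells in the gut. Per the labels, 20 mice were of 3 host genotypes: 5 wild type (WT), 5 heterozygous for DOCK8 (Het) and 10 homozygous, which the sample names call KO. Each mouse gave 3 libraries, named presorted, IgA-negative and IgA-positive, so that 60 libraries entered the work. Per the labels' protocols, the bacteria were lysed by bead beating, DNA was taken up by phenol-chloroform and precipitated, and amplicons of variable region 4 (V4) were read on an Illumina MiSeq. The labels also list the molecule as total RNA, while the protocol describes DNA. The host gene was not measured in these libraries, so the genotypes rest on the labels.

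The authors deposited 1 table of whole-number read counts per 16S reference taxon and library, which per the file header was exported from a BIOM file. Taxonomy strings in the table run from domain to species. The clustering tool, the reference database and any subsampling are not given in the sources used here. Library totals lay between 18909 and 19986 counts, and each fell short of 20000 by 14 to 148 counts in presorted libraries and by 226 to 1091 in sorted ones. Such totals look like an equal-depth subsample with some reads taken out afterwards, which no source states. Differences in original depth between libraries can then no longer be seen. The table has 3506 reference taxa, of which 1201 are 0 in every library, and 2305 hold 1177944 counts in 197 genera, 78 families and 13 phyla. Chloroplast and mitochondrial sequences (5 counts in 3 taxa) were left out of library sizes and tests. No library fell below the minimum of 1000 counts, and no 2 libraries were identical.

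Counts were summed per genus, with taxa lacking a genus name kept under their parent taxon. Genus counts were tested with the quasi-likelihood F-test of edgeR 4.0.16 (robust, TMM scaling, R 4.3.3), with genera of at least 10 counts in at least 5 libraries, Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Presorted libraries of all genotypes shared 1 fit (20 libraries, 58 genera), and sorted libraries another (40 libraries, 59 genera, 6 groups). A standard error (SE) beside a log2 fold change is that change divided by the square root of its F statistic. The difference in IgA coating between genotypes was tested as the positive-over-negative log2 fold change of one genotype minus that of the other. Single values were compared with exact two-sided permutation tests between genotypes and exact two-sided sign-flip tests of the differences within animals, which cannot go below p = 0.0625 with 5 animals. Community composition was compared by PERMANOVA on Bray-Curtis distances of genus shares. Correlations of fold changes are across genera, which are not independent replicates. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, limma 3.58.1 and DESeq2 1.42.0 were also used.

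The 3 fractions of a mouse carry the same animal number, so the numbers pair the samples. Deviations of the IgA-positive and IgA-negative library of the same animal from their group means correlated at 0.454 to 0.624 in WT, 0.390 to 0.684 in Het and 0.322 to 0.751 in KO, against means of -0.139, -0.139 and -0.061 for other animals. An animal's own number was the best match in 5 of 5, 5 of 5 and 8 of 10 animals. The fit has no block for the animal, and the blocked fit is an alternative.

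The choice of samples, tests, alternatives, 7 bacterial lists and the rule for named genera were fixed before the data were examined. Named genera are those past the threshold with a mean share of at least 0.1% in a group compared (up to 12 per direction), the 10 most abundant genera of presorted libraries, and members of the lists. List names were matched to the table's taxonomy after its names, but not its test results, were seen. The lists hold facultative anaerobes, genera reported as strongly IgA-coated in the mouse gut, small-intestinal residents, clostridial producers of short-chain fatty acids, Bacteroidales that degrade polysaccharides, mucus-associated genera, and reagent and handling contaminants. Alternatives were scaling by library totals, DESeq2, limma on centred log ratios, no filter, other depth minimums, family rank, a fit of only the genotypes compared, the animal as a block, a pooled control, other diversity measures and distances, and leaving out each animal. Fits without animals 28 and 32, permutation tests of single genera, list shares scaled by TMM, and splits that exchange the fractions within animals were added after the data were seen.

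The procedure was tested on simulated counts with known changes. For presorted KO against WT libraries (58 genera, 20 simulations), 18% of 2-fold, 49% of 4-fold and 76% of 8-fold changes were called, and 1.21% of unchanged genera. For IgA-positive against IgA-negative WT libraries (59 genera) the shares were 4%, 25% and 52%, with 0.35% of unchanged genera. For the difference in coating between KO and WT they were 2%, 16% and 35%, with 0.12%. PERMANOVA with 5 against 5 libraries gave p under 0.05 in 3 of 60 simulations without change and 60 of 60 with 10 genera changed 6-fold, and the Shannon index in 2 and 27. Shares of single libraries carry 95% Wilson intervals, and a count of 0 is read as allowing up to 3 counts. Both cover counting error only, since reads of a PCR product are not independent molecules. Per the labels all 60 libraries carry the same run name, with running numbers in consecutive blocks of WT, Het and KO, so any effect of library order goes with genotype. Cage, litter and age are not given in the sources used here, so no such effect was modelled.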

Results

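Faecal bacteria of 20 mice (5 WT, 5 Het and 10 KO for DOCK8) were profiled by 16S rRNA sequencing before sorting and in an IgA-negative and an IgA-positive fraction of the same animal. Presorted libraries held 19852 to 19986 counts and sorted libraries 18909 to 19774, so a genus at 0.1% rests on about 20 counts. Values are shares of a library's counts, as mean ± SD over animals, unless stated otherwise.

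The presorted libraries show the whole faecal community by host genotype. Segmented filamentous bacteria (Candidatus_Arthromitus, known to attach to the small-intestinal epithelium and to induce IgA) held 1.27% ± 0.778 of counts in KO animals (n = 10), 0.138% ± 0.102 in WT (n = 5) and 0.0832% ± 0.0821 in Het (n = 5). Of the 10 KO animals, 9 lay above every WT and every Het animal. Candidatus_Arthromitus was higher in KO than in Het animals (log2 fold change 4.10, SE 0.95, edgeR adjusted p = 0.0169), the 1 genus of 58 past the threshold in this comparison. Against WT the log2 fold change was 2.99 (SE 0.88), which did not pass (edgeR adjusted p = 0.107). unclassified_Peptococcaceae stood at 0.797% ± 0.294 in KO and 0.383% ± 0.165 in WT (log2 fold change 1.04, SE 0.32, edgeR adjusted p = 0.107).

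edgeR called 0 of 58 genera between KO and WT, where 7 genera had an unadjusted p under 0.05. limma on centred log ratios called 0 as well, while DESeq2 called 2, Candidatus_Arthromitus (adjusted p = 0.00766) and unclassified_Peptococcaceae (adjusted p = 0.0219). With WT and Het animals pooled as the control, edgeR called the same 2 genera (adjusted p = 0.00282 and 0.01). In a test of the shares alone, chosen after the values were seen, Candidatus_Arthromitus differed between KO and WT by exact two-sided permutation (p = 0.00699, adjusted p = 0.0157 over 9 such tests) and between KO and Het (p = 0.00599, adjusted p = 0.0157). Those tests cover this genus alone. An exact permutation test of the log2 share of each of the 58 genera, also added after, did not pass for Candidatus_Arthromitus (adjusted p = 0.0773 against WT and 0.0579 against Het). The call against Het was lost without Het animal 26 (edgeR adjusted p = 0.0574) or Het animal 27 (adjusted p = 0.0719). KO animal 34 was the exception within its group, with 21 of 19971 counts (0.105%, 95% Wilson interval 0.0688 to 0.161).

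**Figure D1:**
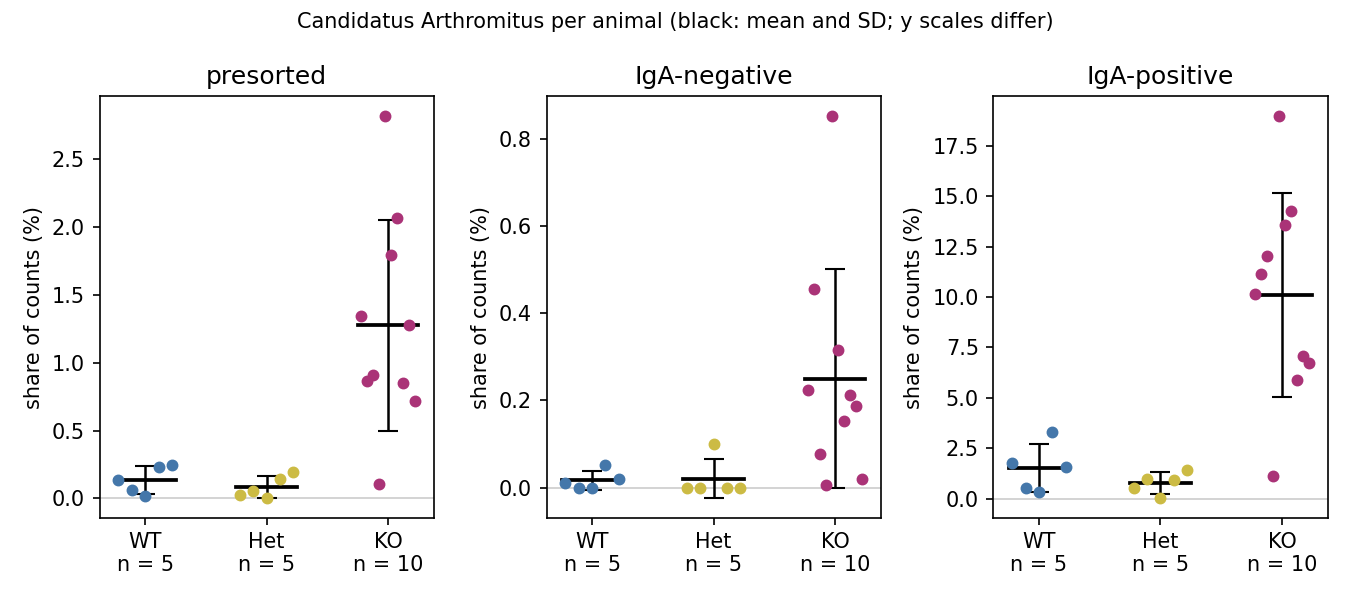
Share of counts (%) of Candidatus Arthromitus in each animal, by genotype (WT n = 5, Het n = 5, KO n = 10), in presorted, IgA-negative and IgA-positive libraries. Points are animals, black lines and bars are mean and SD, the vertical scales differ, and 9 of 10 KO animals lie above the highest WT animal before sorting (means 1.27% and 0.138%).

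The 10 most abundant presorted genera did not pass the test between any pair of genotypes. unclassified_Bacteroidales_S24-7_group, a family of fibre-degrading gut Bacteroidales, held 23.7% ± 2.99 in KO, 24.2% ± 5.12 in WT and 23.7% ± 3.00 in Het animals. Lachnospiraceae_NK4A136_group stood at 11.9% ± 3.60, 10.0% ± 3.49 and 12.8% ± 4.43, and Allobaculum at 8.89% ± 2.53, 8.29% ± 5.57 and 5.51% ± 2.52. Lactobacillus held 9.34% ± 2.29 in KO and 14.1% ± 8.01 in WT (log2 fold change -0.80, SE 0.34, edgeR adjusted p = 0.252). Bifidobacterium held 1.51% ± 1.51 in KO and 4.19% ± 3.84 in WT (edgeR adjusted p = 0.403). The log2 fold changes of the other 5 between KO and WT (Odoribacter 0.23, Alistipes 0.06, unclassified_Ruminococcaceae -0.27, Lachnospiraceae_UCG-006 -0.11 and Bacteroides -0.16) were below their standard errors or close to them. Between Het and WT animals edgeR called 0 genera, with 2 at an unadjusted p under 0.05 (Lactobacillus and Streptococcus), and DESeq2 and limma also called 0.

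Of the 5 phyla with a mean share of at least 0.5%, none differed between genotypes after adjustment. Firmicutes held 52.2% ± 3.99 in KO (n = 10), 52.7% ± 6.91 in WT (n = 5) and 52.5% ± 3.85 in Het animals, and Bacteroidetes 37.6% ± 4.67, 36.5% ± 7.96 and 36.1% ± 6.19. Actinobacteria stood at 2.17% ± 1.58 in KO and 5.39% ± 3.60 in WT (exact two-sided permutation p = 0.0246, adjusted p = 0.123). Proteobacteria stood at 5.79% ± 1.85 and 3.78% ± 1.95 (exact permutation p = 0.0756, adjusted p = 0.189).

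The Shannon index of presorted genera was 2.86 ± 0.084 in KO, 2.74 ± 0.191 in WT and 2.87 ± 0.091 in Het animals, with exact two-sided permutation p of 0.0846 for KO against WT (adjusted p = 0.254), 0.970 for KO against Het and 0.222 for Het against WT. Over 15 fits that each left out 1 animal, the difference between KO and WT ranged from 0.0603 to 0.180. The highest was without WT animal 22 (exact permutation p = 0.017, not adjusted for the choice among fits). The split by genotype took up 10.2% of the Bray-Curtis distances between KO and WT (exact permutation p = 0.150). It took up 10.4% between KO and Het (p = 0.131) and 9.16% between Het and WT (p = 0.683). None passed, and any split of so few animals takes up some share by chance. On Aitchison distances the share for KO against WT, as R2, was 0.124 (exact permutation p = 0.00766). Leaving out single animals gave 0.0836 to 0.144 on Bray-Curtis distances, the highest without WT animal 22 (exact permutation p = 0.044). For KO against Het the range was 0.0840 to 0.139, the highest without Het animal 28 (exact permutation p = 0.032). Both of these p come from 1 of 15 fits, picked for the highest R2, and are not adjusted.

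The sorted fractions ask which bacteria carry IgA. In all 3 genotypes Marvinbryantia, an acetogenic genus of the Lachnospiraceae, was the genus with the lowest adjusted p. It held 10.8% ± 2.20 of the IgA-positive and 0.331% ± 0.249 of the IgA-negative counts in WT animals (n = 5, log2 fold change 5.52, SE 0.56, edgeR adjusted p = 3.43e-10). In Het animals it held 10.7% ± 2.30 and 0.304% ± 0.119 (n = 5, log2 fold change 5.74, SE 0.57, adjusted p = 1.53e-10). In KO animals it held 8.48% ± 2.85 and 0.164% ± 0.093 (n = 10, log2 fold change 6.10, SE 0.41, adjusted p = 1.02e-15). It was higher in the IgA-positive fraction of every animal. Candidatus_Arthromitus rose with log2 fold changes of 6.87 in WT (SE 1.41, edgeR adjusted p = 0.00057), 5.76 in Het (SE 1.34, adjusted p = 0.00333) and 5.83 in KO (SE 0.93, adjusted p = 7.54e-06), and was higher in 5 of 5, 4 of 5 and 10 of 10 animals. In Het animals its 19 IgA-negative counts all came from animal 28, which had 4 IgA-positive counts. The other Het animals had 0 IgA-negative counts, so the size of the Het fold change rests on 1 library.

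Ruminococcaceae_UCG-005 passed in all 3 genotypes as well, though its share lay below 0.1%, so it is named after its values were seen. It had 0 counts in the IgA-negative libraries of WT and Het animals. Its IgA-positive shares of 0.0830% and 0.0541% were at least 26.8-fold and at least 17.4-fold higher than a floor of 3 counts over the group (0.00309% and 0.0031%). In KO animals it held 0.0784% against 0.00358% (log2 fold change 5.01, edgeR adjusted p = 0.000313). Lactobacillus rose in Het animals (18.6% ± 7.41 against 7.08% ± 3.73, log2 fold change 2.00, edgeR adjusted p = 0.00709) and in KO animals (22.2% ± 5.19 against 11.9% ± 2.99, log2 fold change 1.25, adjusted p = 0.0101). WT animals had 22.4% ± 6.33 against 11.7% ± 7.14, higher in 5 of 5 animals, with a log2 fold change of 1.26 that did not pass (edgeR adjusted p = 0.144). unclassified_Lachnospiraceae rose in WT (log2 fold change 2.34, edgeR adjusted p = 0.00899) and KO animals (1.58, adjusted p = 0.0101), and [Eubacterium]_nodatum_group in Het animals (2.90, adjusted p = 0.0484).

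In all, 4 of 59 genera were higher and 0 lower in the IgA-positive fraction of WT animals, 5 and 0 in Het animals, and 10 and 4 in KO animals (edgeR). KO had 10 animals and WT and Het 5 each, so these counts do not compare the genotypes. The further genera that rose in KO animals were unclassified_Erysipelotrichaceae (log2 fold change 1.68), Ruminiclostridium_5 (1.43), Oscillibacter (1.40), unclassified_Peptococcaceae (1.32) and, below 0.1% and so named after its values were seen, Family_XIII_UCG-001 (2.80). Lachnospiraceae_UCG-006 fell in KO animals from 5.06% ± 3.46 of the IgA-negative to 0.933% ± 0.670 of the IgA-positive counts (log2 fold change -1.92, SE 0.56, edgeR adjusted p = 0.0101), and was lower in 10 of 10 animals. Lachnospiraceae_NK4A136_group fell from 10.7% ± 3.59 to 4.26% ± 2.79 (-1.004, SE 0.29, edgeR adjusted p = 0.0101), Parabacteroides from 0.657% ± 0.274 to 0.187% ± 0.116 (-1.49, adjusted p = 0.0101) and Desulfovibrio, a sulfate reducer, from 1.89% ± 1.16 to 0.585% ± 0.464 (-1.31, adjusted p = 0.039). These 4 genera also had lower mean IgA-positive shares in WT and Het animals, where the fit without a block did not call them. With the animal as a block, all 4 passed as lower in WT animals. The edgeR adjusted p were 0.00743, 0.0129, 0.046 and 0.00118, in the order above. In Het animals Desulfovibrio alone of the 4 passed in that fit (edgeR adjusted p = 0.0103). Ratios of positive to negative mean shares in WT and Het were 0.299 and 0.389 for Lachnospiraceae_UCG-006 and 0.378 and 0.467 for Lachnospiraceae_NK4A136_group. They were 0.289 and 0.435 for Parabacteroides and 0.284 and 0.318 for Desulfovibrio.

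TMM scaling moved the log2 fold changes of IgA-positive over IgA-negative up by a median of 0.45 in WT, 0.59 in Het and 0.40 in KO animals relative to library totals, and the values above are relative to that shift. Under library totals the calls split into 3 higher and 2 lower in WT, 4 and 0 in Het, and 4 and 11 in KO, with 3, 4 and 8 genera called under both. With the animal as a block 12 genera passed in WT (7 higher, 5 lower), 15 in Het (11 and 4) and 28 in KO (14 and 14). Lactobacillus passed in WT in that fit (log2 fold change 1.57, adjusted p = 0.0129), and unclassified_Peptococcaceae no longer did in KO (0.88, adjusted p = 0.0739). limma called 7 genera in WT, 3 in Het and 12 in KO, and DESeq2 6, 5 and 20.

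Leaving out single animals ended some of these calls. The calls of Marvinbryantia in all 3 genotypes, Candidatus_Arthromitus in WT and KO, and Lactobacillus, Lachnospiraceae_UCG-006 and Parabacteroides in KO held without any 1 animal. Het animals gave 2 calls, Marvinbryantia and Ruminococcaceae_UCG-005, without animal 29 or 30, which ended those of Candidatus_Arthromitus (edgeR adjusted p up to 0.0746) and Lactobacillus (up to 0.08, also without animal 27), while [Eubacterium]_nodatum_group was lost without 27, 28, 29 or 30 (up to 0.267). KO animals gave 9 calls without animal 33 and 7 without animal 34. The call of Lachnospiraceae_NK4A136_group ended without either (edgeR adjusted p up to 0.123), that of unclassified_Lachnospiraceae without 33, 34 or 40 (up to 0.0707), and that of Oscillibacter without 34, 35 or 40 (up to 0.0919). unclassified_Erysipelotrichaceae lost its call without 31, 38, 39 or 40 (edgeR adjusted p up to 0.0634) and unclassified_Peptococcaceae without 32, 34, 36 or 40 (up to 0.132). Desulfovibrio lost its call without 31, 33, 34, 35, 36, 38 or 39 (edgeR adjusted p up to 0.172) and Ruminiclostridium_5 without any of the 10 (0.0519 to 0.222). In WT the call of unclassified_Lachnospiraceae ended without 21, 22, 23 or 24 (edgeR adjusted p up to 0.128), while Lachnospiraceae_NK4A136_group passed without 21 (log2 fold change -1.38, adjusted p = 0.031).

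**Figure D2:**
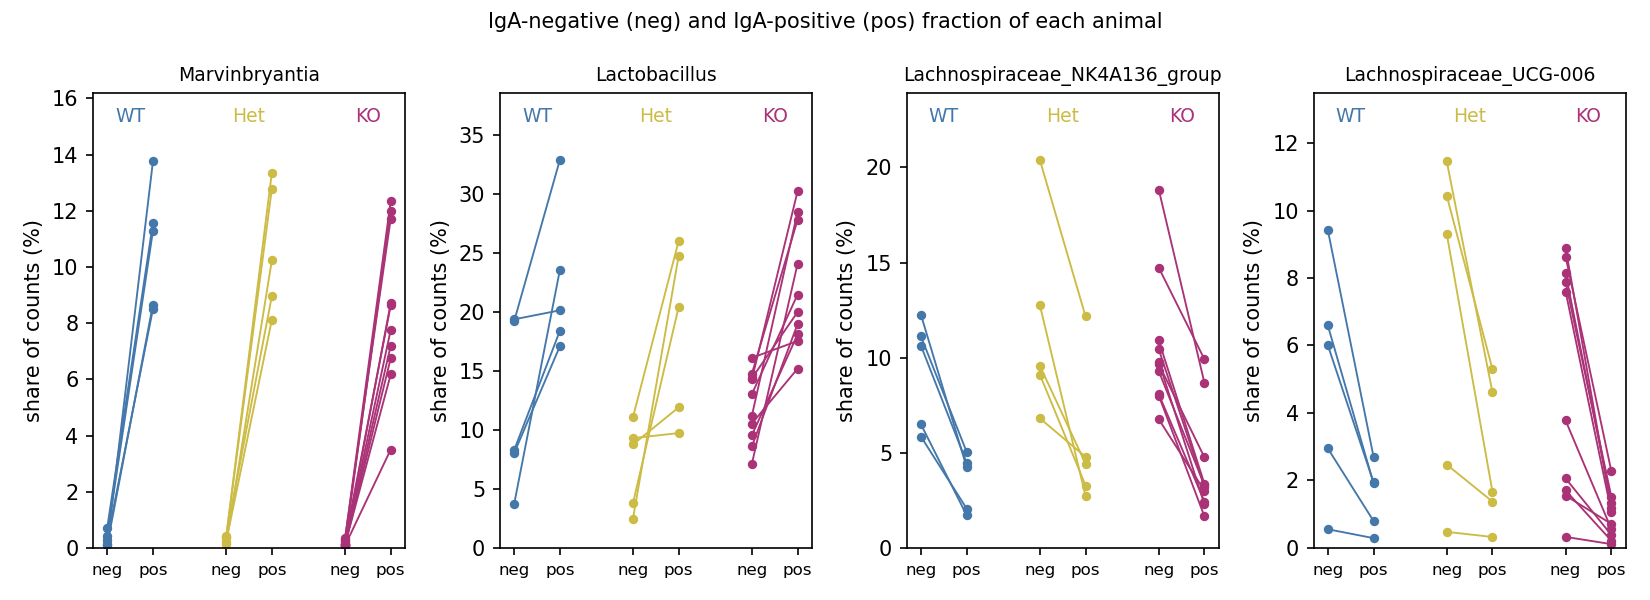
Share of counts (%) of Marvinbryantia, Lactobacillus, Lachnospiraceae_NK4A136_group and Lachnospiraceae_UCG-006 in the IgA-negative (neg) and IgA-positive (pos) library of each animal, joined by a line, for WT (n = 5), Het (n = 5) and KO (n = 10). Marvinbryantia is higher in the positive fraction of every animal, with means of 10.8%, 10.7% and 8.48%.

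Whether the relative coating of single genera differs between genotypes was tested on the positive-over-negative fold changes themselves. These compare shares within fractions, so a change in coating common to all genera could leave them unchanged and is not tested here. Marvinbryantia differed by 0.59 on the log2 scale between KO and WT (SE 0.57), Candidatus_Arthromitus by -1.04 (SE 1.32) and Lactobacillus by -0.01 (SE 0.62), none past the threshold (edgeR adjusted p of 0.980, 0.980 and 0.990). edgeR called 0 of 59 genera for KO against WT, KO against Het and Het against WT, with 0, 2 and 1 genera at an unadjusted p under 0.05. DESeq2, limma and the fit with the animal as a block also called 0 in each. The lowest adjusted p for KO against Het was that of Allobaculum (difference of -1.58, SE 0.61, unadjusted p = 0.0139, edgeR adjusted p = 0.822). Simulated 8-fold differences in coating were called in 35% of cases, so a lack of calls over all genera does not exclude differences of that size. The standard error of a genus bounds its own difference for some genera only. As computed here from the F statistic, it gives no useful bound for Candidatus_Arthromitus between KO and Het (0.066, SE 5.66). The same holds for Ruminococcaceae_UCG-005 between Het and WT (-0.73, SE 1486.8). With the animal as a block, the difference of Candidatus_Arthromitus between KO and Het was -0.97 (SE 1.47, edgeR adjusted p = 0.838).

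Across the 59 genera the positive-over-negative log2 fold changes of WT and KO animals correlated with a Pearson r of 0.828 and a Spearman rho of 0.715. The values were 0.737 and 0.726 for WT and Het, and 0.856 and 0.789 for Het and KO. Among the 40 genera with a mean share of at least 0.1% the Pearson r was 0.940 for WT and KO. Without Marvinbryantia, Candidatus_Arthromitus and Ruminococcaceae_UCG-005, r was 0.686 over 56 genera. Genera are not independent replicates, so no p is given.

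**Figure D3:**
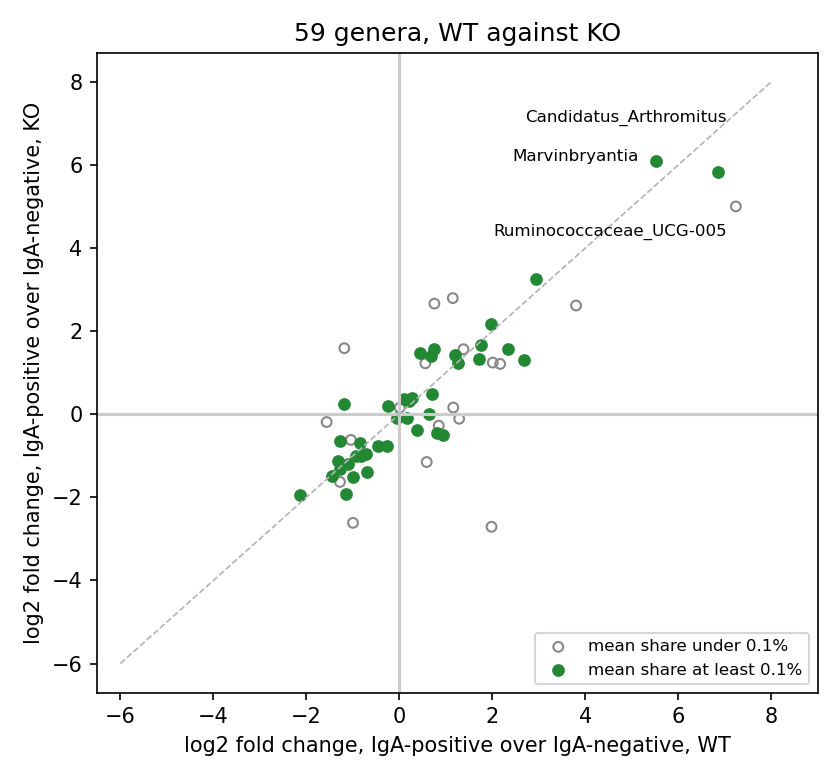
Log2 fold change of IgA-positive over IgA-negative libraries of 59 genera in WT animals (horizontal axis) against KO animals (vertical axis). Filled points are genera with a mean share of at least 0.1%, open points those below, the dashed line marks equal values, r is 0.828 and 48 of 59 genera have the same sign in both genotypes.

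Within the IgA-positive fraction, Candidatus_Arthromitus held 10.1% ± 5.07 in KO (n = 10) and 1.52% ± 1.18 in WT animals (n = 5), with 9 of 10 KO animals above the highest WT animal. The log2 fold change of 2.98 (SE 1.09) did not pass (edgeR adjusted p = 0.543), and edgeR called 0 of 59 genera, with 2 at an unadjusted p under 0.05. limma called 0 and DESeq2 called Candidatus_Arthromitus alone (log2 fold change 3.02, adjusted p = 0.0309). An exact two-sided permutation test of its share, chosen after the values were seen, gave p = 0.004 (adjusted p = 0.0157 over 9 tests of this genus alone). The exact permutation test of the log2 share of each of the 59 genera did not pass for it (adjusted p = 0.0786). Marvinbryantia, Lactobacillus and Lachnospiraceae_NK4A136_group had log2 fold changes of -0.07, 0.27 and 0.38 between KO and WT, within or near their standard errors.

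The lists of bacterial groups were compared as summed shares. In KO animals the small-intestinal residents (Lactobacillus, Allobaculum, Bifidobacterium, Candidatus_Arthromitus, Turicibacter and others) rose from 32.8% ± 6.83 of the IgA-negative to 45.8% ± 9.14 of the IgA-positive counts, higher in 8 of 10 animals (exact two-sided sign-flip adjusted p = 0.0182 over 7 lists). Of their 8 members tested, Candidatus_Arthromitus and Lactobacillus rose and 6 did not pass. Among those 6, mean shares fell for Allobaculum (14.005% to 7.15%, lower in 9 of 10 animals), Turicibacter (3.31% to 1.54%, lower in 8 of 10) and Romboutsia. They rose for Bifidobacterium, Streptococcus and Clostridium_sensu_stricto_1. With the animal as a block, Turicibacter (log2 fold change -0.819, edgeR adjusted p = 0.0353) and Romboutsia (-1.10, adjusted p = 0.0366) passed as lower. Bifidobacterium (1.92, adjusted p = 0.043) and Clostridium_sensu_stricto_1 (2.45, adjusted p = 0.00995) passed as higher in that fit. The rise of the list thus does not hold for every member. The genera reported as strongly IgA-coated rose from 33.98% ± 6.86 to 43.1% ± 5.79 (adjusted p = 0.0308), where Candidatus_Arthromitus and Lactobacillus rose, Desulfovibrio fell and 6 of 9 members did not pass. Allobaculum and Turicibacter, with the lower mean shares given above, are on this list as well. Facultative anaerobes rose from 0.177% ± 0.108 to 0.310% ± 0.217 (adjusted p = 0.0355), most of it Streptococcus at 0.143% and 0.260%. On library totals Bacteroidales polysaccharide degraders fell from 34.1% ± 4.33 to 24.9% ± 5.83 (adjusted p = 0.0182), with Parabacteroides lower and 5 of 6 members not past the test. Mucus-associated genera fell from 3.80% ± 0.799 to 2.00% ± 0.910 (adjusted p = 0.0182), with 0 of 3 members called. Clostridial short-chain fatty acid producers (adjusted p = 0.582) and reagent contaminants (adjusted p = 0.408) did not pass, though Oscillibacter, Ruminiclostridium_5 and unclassified_Lachnospiraceae of the former rose. These list shares are on library totals, where the median genus of KO animals had a log2 fold change of -0.41, while the calls of members use TMM scaling. With the TMM factors applied to the lists, an alternative chosen after the values were seen, Bacteroidales polysaccharide degraders no longer differed past the threshold (-0.05 on the log2 scale, lower in 7 of 10 animals, exact sign-flip adjusted p = 0.758). Small-intestinal residents (0.91), genera reported as strongly IgA-coated (0.78), facultative anaerobes (1.09) and mucus-associated genera (-0.61) still passed, and reagent contaminants did as well (0.72, exact sign-flip adjusted p = 0.041).

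In WT and Het animals no list could pass, since 5 pairs are too few for an exact sign-flip test to reach 0.05. Bacteroidales polysaccharide degraders stood at 28.8% ± 4.27 of the IgA-positive and 35.7% ± 4.96 of the IgA-negative counts in WT animals, lower in 5 of 5 (0.13 higher on the log2 scale with TMM factors), and small-intestinal residents at 38.8% ± 5.92 and 30.0% ± 14.1. Het animals had 33.2% ± 5.39 and 20.2% ± 3.30 of small-intestinal residents. The difference between fractions did not differ between genotypes for any list (lowest adjusted p = 0.177, facultative anaerobes, KO against WT, exact permutation).

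In presorted libraries the facultative anaerobes were lower in KO (0.0891% ± 0.0489) than in WT animals (0.227% ± 0.134, exact two-sided permutation p = 0.00633, adjusted p = 0.0443). Most of the list was Streptococcus, at 0.0721% ± 0.0389 and 0.191% ± 0.142. On the log2 scale the list did not pass (exact permutation adjusted p = 0.175). No other list passed between presorted libraries of any pair of genotypes, and the lowest adjusted p among them was 0.0793. Adjusted over the list alone, edgeR called Candidatus_Arthromitus between KO and WT in both lists that hold it. Streptococcus was the 1 tested member of its list, so that adjustment left its p as it was. This unadjusted edgeR p lay under 0.05 between KO and WT and between Het and WT, where no genus passed over all genera. The same holds for Streptococcus between the fractions of WT animals, where it did not pass over all genera. Adjusted over its list alone, [Eubacterium]_nodatum_group was not called between the fractions of Het animals. All other list members had the same calls adjusted over the list alone as over all genera.

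The IgA-positive and IgA-negative communities of an animal lay at a Bray-Curtis distance of 0.384 ± 0.069 in KO (n = 10), 0.322 ± 0.064 in WT (n = 5) and 0.362 ± 0.072 in Het animals (n = 5), with exact two-sided permutation p of 0.113 for KO against WT, 0.584 for KO against Het and 0.373 for Het against WT. The IgA-negative library lay closer to its own presorted library (0.154 ± 0.021 in WT, 0.164 ± 0.023 in Het and 0.188 ± 0.034 in KO) than the IgA-positive library did (0.295 ± 0.064, 0.318 ± 0.043 and 0.370 ± 0.065), a difference that was not tested. IgA-positive libraries were closer on average to those of other animals of their genotype than to the IgA-negative library of the same animal in 10 of 10 KO, 5 of 5 WT and 3 of 5 Het animals. The Shannon index of genera differed between fractions by -0.036 in WT, -0.094 in Het and 0.003 in KO animals (exact two-sided sign-flip p of 0.688, 0.125 and 0.971). Over reference taxa instead of genera, the index was lower in the IgA-positive than in the IgA-negative fraction, at 3.84 and 4.06 in WT, 3.85 and 4.16 in Het, and 3.67 and 3.97 in KO animals. Shannon diversity IgA-positive minus IgA-negative in KO was then -0.298 (exact two-sided sign-flip p = 0.0137), while 5 pairs are too few to pass in WT and Het.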

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

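The tests of explanations in this part were chosen after the results were seen, and the comparison of each sample with its group was chosen before. A sample is listed where its gap to the nearest other sample of its group exceeds Dixon's 95% limit. This was so in 20 of 273 groups of values (7.33%), where chance gives about 1 in 20. Shares below are percent of counts, with the range of the other animals of the group in brackets, and counting error is at most 0.644 points. No pair of genotypes had every animal moving in opposite directions between fractions (0 pairs).

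Among Het animals, number 27 had a presorted share of Bifidobacterium of 11.91 (0.296 to 2.464), of Actinobacteria, its phylum, of 13.94 (1.406 to 3.811) and of small-intestinal residents of 31.43 (14.5 to 18.63). Het animal 30 had 7.262 of Bacteroides in the IgA-negative library (0.9202 to 2.692). Among KO animals, number 31 had 5.273 of Bifidobacterium (0.1252 to 2.282) and 5.989 of Actinobacteria (0.7306 to 2.848) before sorting, and 9.419 of Bifidobacterium in the IgA-negative library (0.1476 to 3.622). KO animal 38 had 15.08 of Allobaculum before sorting (6.612 to 10.27), KO animal 39 had 5.076 of Odoribacter in the IgA-positive library (1.223 to 2.17), and KO animal 35 had 0.8537 of Candidatus_Arthromitus in the IgA-negative library (0.005062 to 0.455). WT animal 25 had 0.06045 of reagent contaminants before sorting (0.005011 to 0.02004), which rests on few counts.

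Het animal 28 and KO animal 32 stood out together. Animal 28 had 5.64 of unclassified_Lachnospiraceae before sorting (1.199 to 2.262) and 5.68 in the IgA-negative library (0.3434 to 1.298), and 590 reference taxa before sorting (397 to 423). Its IgA-positive library held 24.27 of Allobaculum (1.467 to 7.197) and 12.17 of Lachnospiraceae_NK4A136_group (2.72 to 4.787), and its IgA-negative library 0.1005 of Candidatus_Arthromitus, with 0 counts in the others. Animal 32 had 564 reference taxa before sorting (381 to 459), and 3.292 of unclassified_Lachnospiraceae (0.3489 to 1.893) and 2.014 of Ruminiclostridium_5 (0.2734 to 0.873) in the IgA-negative library.

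The 2 animals share 120 reference taxa, chosen in presorted libraries, 83 of Lachnospiraceae and 27 of Ruminococcaceae. These taxa made up 27.2% and 24.6% of their presorted counts and at most 0.145% in the other 18 animals. Mixing of reads confined to single libraries is argued against by the sorted libraries of both, where these taxa held at least 14.68%. Mixing that struck every library of both animals alike is not tested by this, and their running numbers are equally spaced in every fraction. The sorted libraries of the other Het and KO animals held at most 0.07609%. That does not test genotype, since the taxa were chosen in the presorted libraries as those shared by these 2 animals. A cage or source common to both animals cannot be told apart from mixing of the material before the sort, or from mixing of all their libraries, since no cage is given. Their presorted libraries lay at a Bray-Curtis distance of 0.2207, against a mean of 0.527 to the other animals and 0.356 among those, and 2 of 189 other pairs lay closer.

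Candidatus_Arthromitus stood higher in KO than in WT presorted libraries (1.27% and 0.138%). IgA-positive material in the KO presorted libraries would bring Marvinbryantia along, by 0.955 points, but its share differed by -0.4864 points (SE 0.197, exact two-sided permutation p = 0.036). Deeper KO presorted libraries could not be tested, since the totals held are near equal (means of 19972.3 in KO and 19945.6 in WT) and original depth cannot be seen. Counting error at the depth held is argued against for 9 of 10 KO animals, whose 95% counting limits lie above those of every WT animal (0.326% at most). A cage or source shared by KO animals cannot be told apart from the genotype, since the labels give no cage, and the Bray-Curtis comparison of KO and WT gave an exact permutation p of 0.1502 while Aitchison distances gave 0.00766. Genotype itself stays among the open explanations.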

How the results depend on the processing

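The fits without animals 28 and 32 and the permutation test of each genus were chosen after seeing the data. Of 396 alternative values of 27 results, 353 kept their direction and side of the threshold or stayed within 1.5 times the reported count. DESeq2 called 2 genera in presorted KO against WT, 2 in KO against Het and 1 in IgA-positive KO against WT. WT and Het pooled gave 2, and family rank 1 for KO against WT. Between fractions, family rank called 1 in WT, 2 in Het and 6 in KO, with fewer taxa tested. limma called 7 in WT and 3 in Het, a fit of the Het libraries alone 1, and the animal as a block 12, 15 and 28. The exact permutation test of each genus called 0 for KO against Het, where edgeR called 1 (5 at an unadjusted p under 0.05), DESeq2 2 and limma 1. Inverse Simpson gave 0.0195 for presorted Shannon diversity KO vs Het and 0.0479 for Shannon diversity IgA-positive minus IgA-negative in WT. The Shannon index of reference taxa gave -0.298 between fractions of KO (exact sign-flip p = 0.0137). Aitchison distances gave an R2 of 0.124 for KO against WT (exact permutation p = 0.00766) and -0.0147 for Bray-Curtis distance between IgA-positive and IgA-negative KO vs Het. Agreement among genera of at least 0.1% was 0.940 (WT and KO) and 0.912 (WT and Het). Without single animals, calls ranged from 0 to 2 for presorted KO against Het, and between fractions from 3 to 4 in WT, 2 to 5 in Het and 7 to 15 in KO. The Shannon differences ranged from 0.0603 to 0.180 (KO against WT), -0.0314 to 0.0224 (KO against Het), -0.0610 to 0.00945 (fractions of WT) and -0.0284 to 0.0264 (fractions of KO). R2 ranged from 0.0836 to 0.144 (KO against WT) and 0.0840 to 0.139 (KO against Het), and the difference in distance between fractions from -0.00726 to 0.0408 (KO against Het). The cause was not tested. Without animals 28 and 32, edgeR called 0, 1 and 0 genera between presorted genotypes, 5 between fractions in Het (4 shared) and 18 in KO (12 shared). Of 2285 alternative values of single genera 2196 were the same, 73 lost and 16 gained a call, and 0 called genera reversed, while 237 values of genera not called had another sign. Most named genera were not called, so most of these values could be the same by staying uncalled. The depth minimums removed no library, so they test nothing, and at this depth a count of 0 allows up to 3.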

Other observations

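The tests of Saccharibacteria, of genera lost in the sort and of the IgA-coated share were chosen after the results were seen, as were the splits within animals, and the comparison with other splits of the samples was chosen before.

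Saccharibacteria, small bacteria known to live on the surface of other bacteria, had 2 to 21 counts in presorted libraries of KO animals (0.0536% ± 0.0297, n = 10) and 0 to 2 in those of WT (0.00300%) and Het animals (0.00200%). Of the KO animals, 9 of 10 lay above every WT and every Het animal. By exact two-sided permutation the share differed from WT (p = 0.00366) and from Het (p = 0.00333), both with an adjusted p of 0.0220 over 12 tests. After sorting, KO animals held 0.0081% ± 0.0132 in the IgA-negative and 0.0066% ± 0.0146 in the IgA-positive fraction, and WT animals 0.0041% ± 0.0056 and 0.0010% ± 0.0023, differences that lie within the SD and were not tested. Halomonas, a genus of the reagent list, held 0.0774% ± 0.0417 of sorted and 0.0118% ± 0.0141 of presorted counts. Rhodococcus held 0.431%, 0.403% and 0.392% in the 3 libraries of WT animal 24.

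Of 58 genera, 21 had a higher share in the presorted library than in both sorted libraries of the same animal more often than the 33.3% chance gives (exact one-sided binomial test, adjusted p under 0.05). Genera entered by their counts before sorting, so those scarce before and common after, such as Halomonas, could not be seen. Rikenella held 0.780% before sorting and 0.372% and 0.289% in the IgA-negative and IgA-positive fractions (20 of 20 animals), and Helicobacter 1.54%, 0.488% and 0.397% (19 of 20). Reagent bacteria are argued against by a share of at most 0.2739% in a sorted library, where diluting Helicobacter as seen would need 68.3%. For 20 of the 21 genera the pooled presorted shares lay above both sorted ones beyond 95% counting limits, but not for Anaerotruncus (lower limit 0.6321%, against an upper limit of 0.661% after sorting). This does not test lower depth of the sorted libraries. The genera were chosen for this difference, the totals held are near equal (means of 19467 sorted and 19963 presorted), and original depth cannot be seen. Losses or gates in the sort could lie behind the 21 genera and cannot be told apart here, since the gates are not given in the sources used here.

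The share of IgA-coated bacteria may be estimated from where the presorted share of Marvinbryantia lies between its shares in the sorted libraries of the same animal. This gave 8.98% ± 1.41 in WT (n = 5), 11.2% ± 5.69 in Het (n = 5) and 7.30% ± 3.06 in KO animals (n = 10). The first test asked whether KO and WT differ, and did not pass (exact two-sided permutation p = 0.264, adjusted p = 0.396 over 3 tests). After that result was seen the question was changed to whether the share in KO is at most 4.49%, the WT mean divided by 2. The ratio of means was 0.8131, and KO lay above that limit by 2.81 points (SE 1.02). This decides nothing, since the limit was set with the values in view and the estimate takes the presorted library as a blend of both sorted ones, which the 21 genera above do not follow.

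Other splits of the samples were drawn to ask whether chance can be excluded, with 100 splits per comparison unless stated otherwise, the real one included. For IgA-positive against IgA-negative libraries the animal numbers pair the samples, so the splits compared exchange the fractions within animals. In KO animals chance can be excluded, as 1 of 100 such splits, the real one, called as many genera (14, highest other 9). WT and Het animals allow 16 such splits each, too few for a share under 0.05 (WT 4 genera, highest other 1, and Het 5 genera, highest other 1, with 1 split as large). Splits drawn without regard to the animals, most of which keep both fractions of some animals together, called at most 1 genus in WT, 3 in Het and 3 in KO. For presorted KO against Het, 2 splits of 100 called as many genera of any name (1, highest other 1). That share is not adjusted for the other comparisons split in this way. The exact permutation test of each genus did not pass for Candidatus_Arthromitus (adjusted p = 0.0579), so chance is not excluded. Where edgeR called 0 genera the splits say nothing about chance, since any split (100 of 100) calls at least 0: presorted KO against WT (7 at an unadjusted p under 0.05, DESeq2 2, limma 0, highest other 1), Het against WT (2 at an unadjusted p under 0.05, DESeq2 and limma 0, highest other 2), IgA-positive KO against WT (2 at an unadjusted p under 0.05, DESeq2 1, limma 0, highest other 1) and the 3 differences in coating (0, 2 and 1 at an unadjusted p under 0.05, DESeq2 and limma 0, highest other 0).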
